A study of Mus musculus with 12 samples.

How the data were processed

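Total RNA of mouse embryonic fibroblasts was hybridised to 12 mouse miRNA arrays, 2 for each of 6 groups, after Cy3 labelling of 100 ng per array, per the labels' protocols. Genotype, treatment and replicate number were taken from the sample labels. Spot intensities were deposited as written by Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes, with the local background and spatial trend subtracted, on a linear scale and with no scaling between arrays, per the file headers. The deposited series table holds log2 values, and each equalled log2 of the scanner software's summed signal of a detected miRNA on the same array.

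The 13715 spots per array included 715 control spots, which were left out with spots marked as outliers, and no spot was saturated. Spots of a probe were averaged, for 1857 probes of 650 miRNAs. Each array was divided by its 75th percentile over the 87 probes well above background on all arrays. A floor was then set at 0.0309, the median over arrays of the lowest scaled signal among probes well above background, and log2 was taken. A miRNA's value was the mean over its probes that were well above background on both arrays of at least 1 group, which left 175 miRNAs. Where a group was not well above background on any array, the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest signal well above background and the miRNA's own, and given as at least N-fold. Such a bound is not strict where, on 1 array of the dim group, the lowest signal well above background exceeds the brighter group's level. The scanner software's flag also accepts signals below the floor on arrays with a low background. Counts of measured miRNAs therefore ask for the flag and for no used probe at the floor, a definition chosen after the data were seen; by the flag alone, 33 in place of 30 of the calls for wild type cells at 12 h, and 39 in place of 21 for the untreated genotypes, would count. Among called miRNAs, none had used probes that moved in opposite directions. A miRNA with 1 used probe, or with probes that stayed at the floor, could not show this, so the count says little about probe agreement. miRNA names are those of the array design, and the scanner files name no genome build, so no coordinates are given.

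limma 3.58.1 in R 4.3.3 was fitted to all 6 group means (lmFit and eBayes, 6 residual and 1.16 prior degrees of freedom), with Benjamini-Hochberg adjustment within each of 12 comparisons and a threshold of 0.05. The tests, the rule for named miRNAs, 21 miRNA lists and most alternatives were fixed before the data were examined. The rule named, among miRNAs past the threshold whose groups did not overlap, the 12 largest rises and falls, the 5 smallest p where fewer than 5 passed, and any tested list member. Fitted sizes of miRNAs at the floor have no order, so the examples given first are measured ones, a choice made after the data were seen. Values at the floor do not vary between replicates, which lowers the spread and the p-values of miRNAs with groups there. Lists with at least 3 tested members, 14 of them, were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, over 168 tests in all. Alternatives covered scaling, background correction, filters, floor, probe rule, blocks and each array left out. normexp was run on the median spot signal, since the planned mean signal is not among the columns used here.

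The fit was tested on simulated data with the observed means and spreads of 175 miRNAs. For 12 h of tunicamycin in wild type cells it recovered 38.2% of changes of 0.5, 74.2% of changes of 1 and 87% of changes of 2 log2 units, with a mean of 1.02 false calls. For the difference of the 12 h responses it recovered 20.8%, 52.8% and 81.8%. camera recovered a list of 10 miRNAs shifted by 0.5 in 100% of 50 simulations, with 5 false lists. The simulation holds no floor, no scanning runs and no correlation between miRNAs. It does take over spreads that the floor had lowered, which makes changes in those miRNAs easier to recover. Its list result therefore need not hold for lists of correlated miRNAs.

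Slides and scanning runs were read from the file headers. Slide 1 held the 4 untreated and slide 2 the 8 treated arrays, the untreated replicates scanned in runs 1 and 2 and the treated replicates in runs 3 and 4. On the 4 arrays of run 4, 85 to 144 miRNAs were well above background, against 129 to 171 in run 3. The SD over miRNAs of the difference between replicates was 0.203 and 0.206 for the untreated groups and 0.715 to 1.19 for the treated ones.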

Results

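The miRNA content of mouse embryonic fibroblasts was measured on 12 single-colour arrays with probes for 611 mouse and 39 viral miRNAs. The cells were wild type or lacked ATF6a, a membrane-bound transcription factor of the endoplasmic reticulum that is cleaved and moves to the nucleus when unfolded proteins accumulate. Each genotype was left untreated or given 2 ug/mL tunicamycin, an inhibitor of N-linked glycosylation that causes such accumulation, for 12 or 24 h. The 6 groups held 2 arrays each, from experiments that the labels describe as independent. The design addresses which miRNAs responded to tunicamycin and whether the response depended on ATF6a. The array has no probe for the ATF6a transcript, so the genotype labels could not be checked against the targeted gene. Between 85 and 171 miRNAs per array were well above background, and 175 were tested. Changes are log2 differences ± SE with n = 2 arrays per group, and the number of arrays limits their precision. A miRNA is called measured in a comparison where it was well above background, with no used probe at the signal floor, on every array compared.

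In wild type cells, 12 h of tunicamycin lowered the let-7 family member let-7i, with a change of -1.34 ± 0.14 (limma, adjusted p = 0.000378). miR-26a changed by -1.44 ± 0.20 and miR-23b by -1.55 ± 0.21. Members of the miR-17~92 cluster, known for promoting proliferation, rose, with miR-19b at 0.92 ± 0.18 and miR-92a at 1.16 ± 0.25. miR-1224, which stands in the list of GC-rich miRNAs abundant on arrays, rose by 1.89 ± 0.26 (limma, adjusted p = 0.00123). For each of these, both treated arrays lay beyond both untreated ones, which the rule for named miRNAs requires. The same held for 130 of all 175 tested miRNAs (74.3%), against a chance share of 33.3%.

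**Figure D1:**
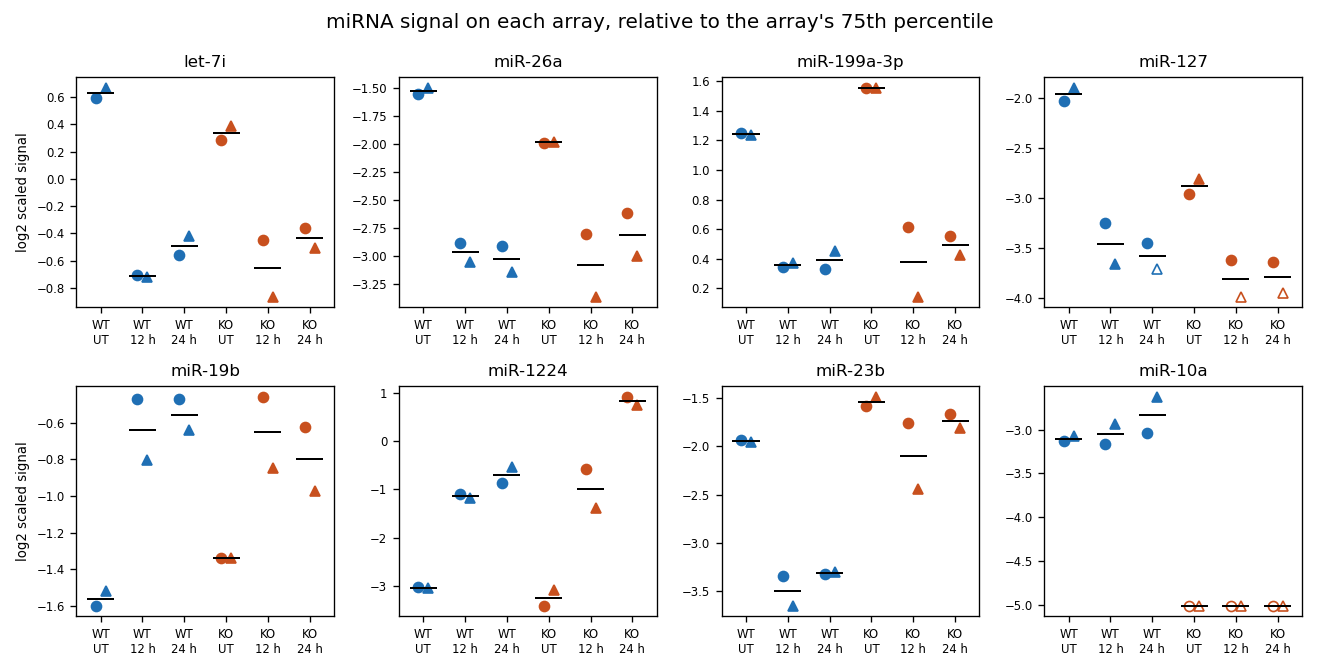
Log2 signal relative to the array's 75th percentile (vertical axis, with its own range in each panel) of 8 miRNAs in the 6 groups (horizontal axis; WT wild type, KO ATF6a knockout, UT untreated, 12 h and 24 h of tunicamycin), with circles for replicate 1, triangles for replicate 2, bars for their mean, and open symbols where the miRNA was not well above background or had a probe at the floor. let-7i changed by -1.34 and miR-1224 by 1.89 at 12 h in wild type cells, and miR-10a lay at the floor on all knockout arrays.

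Among the 16 tested mesenchymal and fibroblast miRNAs, 10 fell and 1 rose at 12 h, and 11 were lower when adjusted over the list alone (camera adjusted p = 0.268; adjusted p = 0.847 with an estimated correlation), and their median of -0.68 was -0.20 with normexp. Those that fell included miR-143 at -1.30 ± 0.27, miR-21 at -1.03 ± 0.18 and miR-199a-3p at -0.89 ± 0.14. Of 10 tested members of the miR-17~92 and paralogous clusters, 5 rose and none fell, also 5 when adjusted over the list alone (camera adjusted p = 0.000757; adjusted p = 0.534 with an estimated correlation). Their median of 0.61 was 0.087 when scaled on all probes and 0.0989 with quantile normalization. Of 33 tested miRNAs of the imprinted Dlk1-Dio3 cluster, 27 fell, 28 when adjusted over the list alone (camera adjusted p = 9.07e-06; adjusted p = 0.0952 with an estimated correlation). The median change of that cluster was -0.70, or -0.50 with miRNAs lost to background at their bound and -0.13 with normexp, and its measured members included miR-127 at -1.49 ± 0.19 and miR-379 at -1.25 ± 0.25. miR-127 turned to 0.89 with the scanner software's summed signal and 1.32 in the deposited table. miR-99a was not well above background on either treated array and was at least 2.01-fold lower (limma, adjusted p = 5.27e-05). Both treated values lay at the floor, which removes their spread and lowers this p-value. miR-210, known to respond to hypoxia, was 1.41-fold lower by the same bound (limma, adjusted p = 1.33e-05), with its treated values also at the floor. Its bound is not strict and rests on treated replicate 1. On treated replicate 2 the lowest signal well above background, -3.67, exceeded the untreated miR-210 levels of -3.86 and -3.83. Signs of RNA quality moved too: of 4 miRNAs annotated as pieces of abundant RNAs, miR-689 was 2-fold higher by its bound. That bound is not strict, since miR-689 was not measured on treated replicate 2. The median of that list, 0.53, turned to -0.14 when scaled on all probes (camera adjusted p = 0.0378; adjusted p = 0.305 with an estimated correlation). In all, 11 miRNAs were higher and 67 lower, and 30 of these 78 were measured on all 4 arrays. In 19 of the 78 at least 1 of these arrays lay at the floor, so their p-values rest in part on a spread lowered by it. The count was 15 (0 higher, 15 lower) with quantile normalization, 29 (1 higher, 28 lower) with the summed signal, 5 (1 higher, 4 lower) with normexp, and in limma 0 when scaled on all probes, with 13 at an unadjusted p under 0.05. All untreated arrays lay on 1 slide and all treated ones on another, so treatment and slide cannot be told apart.

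After 24 h in wild type cells, let-7i changed by -1.12 ± 0.14, miR-26a by -1.50 ± 0.20 and miR-199a-5p by -1.26 ± 0.23. miR-19b rose by 1.01 ± 0.18, miR-20b by 0.86 ± 0.11 and miR-1224 by 2.32 ± 0.26 (limma, adjusted p = 0.000601). Of the mesenchymal and fibroblast list, 9 of 16 fell, 10 when adjusted over the list alone (camera adjusted p = 0.3; adjusted p = 0.917 with an estimated correlation), and its median of -0.63 was -0.0205 with normexp. Of the miR-17~92 list, 5 of 10 rose, 5 when adjusted over the list alone (camera adjusted p = 0.000574; adjusted p = 0.805 with an estimated correlation). In the Dlk1-Dio3 cluster, 28 of 33 fell, 29 when adjusted over the list alone (camera adjusted p = 1.93e-08; adjusted p = 0.0341 with an estimated correlation), with a median of -0.70 that turned to 0.14 with normexp. Of these 33 only miR-299*, miR-300 and miR-379 were measured on all 4 arrays. Background or the floor therefore limits the sizes of the others and the median. miR-689 was not well above background in untreated cells and was at least 4.76-fold higher. In all, 13 miRNAs were higher and 59 lower, 25 of these 72 measured on all 4 arrays. The count was 11 (0 higher, 11 lower) with quantile normalization, 27 (2 higher, 25 lower) with the summed signal, 9 (6 higher, 3 lower) with normexp, and in limma 0 when scaled on all probes, with 11 at an unadjusted p under 0.05; slide and treatment cannot be told apart here either.

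Between 12 and 24 h in wild type cells, miR-689 rose by 1.25 ± 0.15 and miR-148a by 0.80 ± 0.12, neither measured on all 4 arrays. miR-689 turned to -0.27 with the summed signal and -0.94 in the deposited table, and miR-148a to -0.12 in the latter. The next by p did not pass: miR-301a at 0.75 ± 0.16, miR-96 at 0.43 ± 0.10 and miR-34a at 0.46 ± 0.10, all of the other sign in the deposited table (-0.0541, -0.38 and -0.24). The p53-responsive miR-34 family, of 3 tested members, passed as a list (camera adjusted p = 0.0141; adjusted p = 0.582 with an estimated correlation; camera adjusted p = 0.0304 with run as a block) with none of its members passing alone. The 2 calls became 0 in limma without replicate 2 of the 12 h or of the 24 h wild type arrays, with 21 and 9 at an unadjusted p under 0.05, and 7 without either 12 h knockout array, and 5 passed with run as a block.

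In ATF6a knockout cells, miR-199a-5p changed by -1.35 ± 0.23 and miR-199a-3p by -1.18 ± 0.14 at 12 h (limma, adjusted p = 0.00916 and 0.0018), and miR-214, encoded beside miR-199a, by -1.29 ± 0.19. let-7i changed by -0.996 and miR-26a by -1.10 ± 0.20. miR-1224 rose by 2.26 ± 0.26, miR-1895 by 1.52 ± 0.29 and miR-19b by 0.68 ± 0.18. miR-26a turned to 0.12 with the summed signal and 0.40 in the deposited table, and miR-19b to -0.71 when scaled on all probes. Of the mesenchymal and fibroblast list, 7 of 16 fell, 9 when adjusted over the list alone (camera adjusted p = 0.000755; adjusted p = 0.536 with an estimated correlation), and its median of -0.59 was -0.15 with normexp. Of the miR-17~92 list, 2 of 10 rose (camera adjusted p = 0.00222; adjusted p = 0.536 with an estimated correlation), and its median of 0.32 turned to -0.50 with quantile normalization and -0.76 when scaled on all probes. In the Dlk1-Dio3 cluster, 4 of 33 fell. The RNA quality list moved beside these (camera adjusted p = 0.00518; adjusted p = 0.204 with an estimated correlation), with miR-689 rising by 1.57 but turning to -1.22 with the summed signal, the list's median of 0.72 turning to -0.67 when scaled on all probes and -0.24 with the summed signal. In all, 5 miRNAs were higher and 25 lower, 12 of these 30 measured on all 4 arrays. The count was 11 (0 higher, 11 lower) with quantile normalization, 13 without untreated replicate 2, 72 without treated replicate 1, and in limma 0 when fitted to these groups alone, with 34 at an unadjusted p under 0.05, and 0 when scaled on all probes, with 10.

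At 24 h in the knockout, miR-214 changed by -1.41 ± 0.19 and miR-199a-5p by -1.39 ± 0.23, while miR-1224, of the GC-rich list, rose by 4.08 ± 0.26 (limma, adjusted p = 6.36e-05). let-7i changed by -0.77 ± 0.14 and miR-322 by -0.91 ± 0.14. miR-135a* was not well above background in untreated knockout cells and was at least 4.54-fold higher. miR-689, of the RNA quality list, rose by 2.86 ± 0.15 with the smallest p (limma, adjusted p = 3.58e-05). It lay at the floor on untreated replicate 1 and next to it on replicate 2, which limits that size. The median change of the RNA quality list was 0.0025, and its member miR-690 was lower on both treated arrays than on both untreated ones. Of the mesenchymal and fibroblast list, 5 of 16 fell, 10 when adjusted over the list alone (camera adjusted p = 0.000438; adjusted p = 0.551 with an estimated correlation), and its median of -0.55 was -0.0282 with normexp. The miR-17~92 list passed with none of its members passing alone (camera adjusted p = 0.0322; adjusted p = 0.9 with an estimated correlation), and its median of 0.21 turned below 0 with quantile normalization (-0.0342) and when scaled on all probes (-0.42). In all, 4 miRNAs were higher and 14 lower, 8 of these 18 measured on all 4 arrays. The count was 4 (2 higher, 2 lower) with normexp, 9 (1 higher, 8 lower) with the summed signal, 8 without 24 h replicate 2, 32 without either 12 h knockout array, and in limma 0 when scaled on all probes, with 11 at an unadjusted p under 0.05.

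From 12 to 24 h in the knockout, miR-1224 rose by 1.81 ± 0.26, and was the only one of 4 passing miRNAs measured on all 4 arrays. miR-135a* rose by 1.79, miR-689 by 1.29 and miR-148a by 0.99, and miR-193b, at 0.45 ± 0.09, did not pass. miR-689 turned to -0.48 in the deposited table. The miR-34 family passed as a list (camera adjusted p = 0.0468; adjusted p = 0.929 with an estimated correlation; camera adjusted p = 0.0824 with run as a block) with no member passing alone, and its median of 0.56 turned to -0.13 with the summed signal. The count was 56 without 12 h knockout replicate 1, 8 with run as a block, and in limma 0 without 24 h replicate 1, with 15 at an unadjusted p under 0.05.

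Untreated knockout cells held less of the Dlk1-Dio3 miRNAs than untreated wild type cells. Of 33 tested members, 27 were lower, 31 when adjusted over the list alone, and none was higher (camera adjusted p = 1.26e-12; adjusted p = 0.0101 with an estimated correlation; camera adjusted p = 7.59e-11 with run as a block). miR-127 differed by -0.92 ± 0.19 (limma, adjusted p = 0.00921), miR-379 by -1.05 ± 0.25 and miR-410 by -1.06 ± 0.19, knockout minus wild type. The list's median was -0.81, and -0.81 in both scanning runs, but -0.35 with normexp and -0.42 when scaled on all probes. miR-129-3p differed by -1.91 ± 0.24, miR-148a by -1.19 ± 0.12 and miR-155 by -0.94 ± 0.15. miR-10b, encoded in a Hox gene cluster, was higher in the knockout at 0.76 ± 0.17. miR-10a, encoded in another Hox cluster, lay at the floor on both knockout arrays, and its fitted difference of -1.91 is limited by that floor. In the deposited table miR-129-3p turned to 0.13 and miR-10a to 0.90, and miR-10a to 0.34 with the summed signal. The miR-232724 clusters were higher as a list (camera adjusted p = 0.00276; adjusted p = 0.671 with an estimated correlation; camera adjusted p = 0.000989 with run as a block), with miR-27b passing alone at 0.66 ± 0.18. In all, 6 miRNAs were higher and 43 lower, 21 of these 49 measured on all 4 arrays, and 56 passed with run as a block. The count was 12 (4 higher, 8 lower) with quantile normalization, 1 (0 higher, 1 lower) with normexp, 8 with the summed signal, and in limma 0 when scaled on all probes, with 5 at an unadjusted p under 0.05. Every wild type array had row position 1 and every knockout array 2 on its slide, so genotype and position cannot be told apart.

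Under tunicamycin, miR-23b was higher in the knockout by 1.39 ± 0.21 at 12 h and 1.57 ± 0.21 at 24 h (limma, adjusted p = 0.00666 and 0.00309). At 12 h miR-34a, a p53-responsive miRNA, was higher by 0.48 ± 0.10. At 24 h miR-1224 was higher by 1.54 ± 0.26, and miR-96 differed by -1.03 ± 0.10 and miR-322 by -0.71 ± 0.14. miR-689 was higher there by 0.62, and turned to -0.0786 with the summed signal. The Dlk1-Dio3 cluster passed as a list at 12 h, with a median of -0.26 and no member passing alone (camera adjusted p = 0.00493; adjusted p = 0.408 with an estimated correlation; camera adjusted p = 0.00488 with run as a block). The 12 h comparison had 6 higher and 7 lower miRNAs, 2 of them measured on all 4 arrays, and the 24 h comparison 8 and 9, with 6 measured; with run as a block 19 and 21 passed. In limma 0 passed at either time with quantile normalization, with 2 and 9 at an unadjusted p under 0.05. The 12 h count was 6 without wild type 12 h replicate 2, 35 without knockout 12 h replicate 1 and 23 without its replicate 2, and the 24 h count 9 without wild type 24 h replicate 2, 10 without knockout 24 h replicate 2 and 29 without either 12 h knockout array.

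Averaged over the 3 conditions, miR-23b was higher in the knockout by 1.12 ± 0.12 and miR-34a by 0.29 ± 0.06, while miR-140, known from cartilage, differed by -0.76 ± 0.17 (limma, adjusted p = 0.00962). Of the Dlk1-Dio3 cluster, 27 of 33 were lower (camera adjusted p = 4.32e-09; adjusted p = 0.0275 with an estimated correlation; camera adjusted p = 6.77e-08 with run as a block). The miR-232724 clusters were higher as a list (camera adjusted p = 0.0206; adjusted p = 0.663 with an estimated correlation; camera adjusted p = 0.0203 with run as a block). In all, 13 miRNAs were higher and 47 lower, 8 of these 60 measured on all 12 arrays, and 61 passed with run as a block. The count was 1 (0 higher, 1 lower) with quantile normalization, 6 (0 higher, 6 lower) with normexp, 2 (1 higher, 1 lower) with the summed signal, and in limma 0 when scaled on all probes and 0 in the deposited table, with 5 and 10 at an unadjusted p under 0.05.

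Across miRNAs, the 12 h responses of both genotypes correlated with a Pearson's r of 0.88 and a Spearman's rho of 0.75 over 175 miRNAs, and an r of 0.90 over the 52 measured on all arrays. At 24 h r was 0.75 and rho 0.72. Leaving out 13 miRNAs that were higher in the last scanning run, r was 0.76 at 12 h and 0.68 at 24 h over 162 miRNAs, an alternative chosen after the data were seen. At 12 h 22 miRNAs fell in both genotypes, among them let-7i and miR-199a-3p, and 5 rose in both, among them miR-1224 and miR-19b, where independent lists would share 9.57 and 0.314. At 24 h 13 fell and 2 rose in both, where 4.72 and 0.297 would be shared, and 1, miR-148a, changed in opposite directions, at -0.82 ± 0.12 in wild type and 0.61 ± 0.12 in knockout cells; none did at 12 h. On replicate 2 of the 24 h arrays of both genotypes miR-148a was not measured, so background limits both of these sizes. The knockout change of miR-148a turned to -0.0194 when scaled on all probes. miRNAs are not independent replicates, and both genotypes share the slides and runs.

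**Figure D2:**
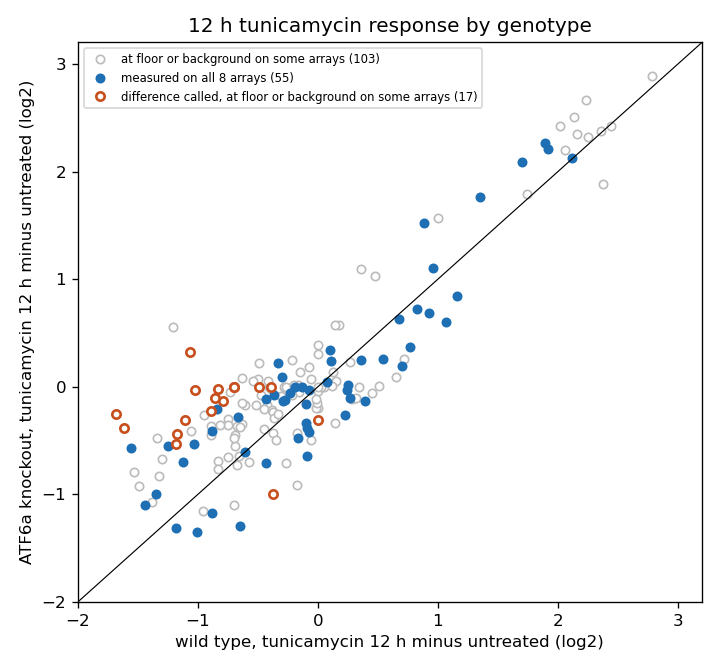
Log2 change after 12 h of tunicamycin in wild type (horizontal axis) and ATF6a knockout cells (vertical axis), with a point per tested miRNA and the line of equal change. Filled points were measured on all 8 arrays and open ones were not; the 17 open points with a bold orange rim passed the test of the difference between genotypes.

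The test of a difference between the 12 h responses picked out 17 miRNAs, of which 0 were measured on all 8 arrays. In 8 of them all treated arrays of both genotypes lay at the floor, miR-222 and miR-146b included, so that the value restates the difference between the untreated genotypes and no difference in response was measured. Among the others the fitted wild type change was the more negative, including miR-99a, miR-148a, which turned to 1.04 in the deposited table, and miR-434-3p of the Dlk1-Dio3 cluster. Of 9 called members of that cluster, 4 lay at the floor in this way. The cluster's median difference, wild type minus knockout, was -0.50, and -0.53 and -0.46 by replicate number (camera adjusted p = 4.55e-08; adjusted p = 0.0387 with an estimated correlation; camera adjusted p = 1.49e-06 with run as a block), or -0.49 without the 5 members at the floor on all treated arrays, but -0.18 with normexp and -0.21 when scaled on all probes. When only the 55 measured miRNAs were tested, limma called 0, with 2 at an unadjusted p under 0.05. With run as a block 12 passed, and in limma 0 with quantile normalization, with 14 at an unadjusted p under 0.05. The count was 10 without wild type 12 h replicate 2, 33 without knockout 12 h replicate 1 and 34 without its replicate 2.

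The test of the 24 h responses picked out 23 miRNAs, 9 of them at the floor on all treated arrays, where no difference in response was measured. Those measured on all 8 arrays were miR-1224, of the GC-rich list, at -1.75 ± 0.36, miR-23b at -1.17 ± 0.30 and miR-20b at 0.59 ± 0.15, wild type minus knockout. miR-20b turned to -0.43 with the summed signal and -0.41 in the deposited table. Of the Dlk1-Dio3 cluster 10 members passed, all with the more negative fitted change in wild type and 5 of them at that floor (camera adjusted p = 1.25e-08; adjusted p = 0.032 with an estimated correlation; camera adjusted p = 9.69e-08 with run as a block). The cluster's median of -0.52 turned to 0.0175 when scaled on all probes and was -0.011 with normexp. The miR-17~92 list had the higher change in wild type (camera adjusted p = 0.0221; adjusted p = 0.87 with an estimated correlation; camera adjusted p = 0.0109 with run as a block), with miR-20b passing alone. Tested among the 60 measured miRNAs alone, limma called 0, with 4 at an unadjusted p under 0.05; 22 passed with run as a block, and 0 with quantile normalization, with 16 at an unadjusted p under 0.05. The count was 12 or 14 without untreated wild type replicate 1 or 2, 14 without 24 h wild type replicate 1, 15 without untreated knockout replicate 2, 11 or 15 without 24 h knockout replicate 1 or 2, and 45 without either 12 h knockout array.

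Of 58 marker miRNAs of 6 other cell types on the array, none was tested, since none was well above background on both arrays of any group, and 4 were well above it on at least 1 array. Of 14 tested miRNAs linked to the unfolded protein response, 1 rose, miR-1224, and 4 fell in wild type cells at 12 h (camera adjusted p = 0.622; adjusted p = 0.847 with an estimated correlation); 13 of the 14 tested members also stand in another list. That list had higher values in untreated knockout cells (camera adjusted p = 0.0181, or 0.835 with an estimated correlation and 0.0095 with run as a block), with a median of 0.16 that turned to -0.0149 with normexp. The difference of its responses, wild type minus knockout, passed at 12 h (camera adjusted p = 0.00688, or 0.955 with an estimated correlation and 0.00319 with run as a block). It also passed at 24 h (camera adjusted p = 0.0431, or 0.87 with an estimated correlation and 0.0254 with run as a block), where the median of 0.19 was 0.0098 with the summed signal. The median response was below 0 in both genotypes, at -0.17 in wild type and -0.25 in knockout cells at 12 h, and -0.027 and -0.17 at 24 h. Under tunicamycin the median genotype difference was 0 at both times. These differences share the untreated arrays, so they show no rise of the list in wild type cells. Of 3 tested miRNAs whose precursors are cleaved by the stress sensor IRE1, 1 fell, miR-34a (camera adjusted p = 0.622; adjusted p = 0.847 with an estimated correlation). Of 5 GC-rich miRNAs, 2 rose in wild type cells at 12 h, miR-1224 and miR-1895 (camera adjusted p = 0.00315; adjusted p = 0.0961 with an estimated correlation), and 2 in the knockout (camera adjusted p = 0.000629; adjusted p = 0.0739 with an estimated correlation). At 24 h in the knockout that list had 1 higher member (camera adjusted p = 0.0217; adjusted p = 0.312 with an estimated correlation), and its median turned from 0.59 to -0.0511 when scaled on all probes. Of 9 let-7 family members, let-7i fell and let-7e rose, at 0.70 ± 0.21, in wild type cells at 12 h. The miR-29 (0.722), miR-30 (0.991), miR-34 (0.622) and miR-232724 (0.622) lists did not pass there by their camera adjusted p, nor did the list of miR-15, miR-16, miR-322 and miR-503 and their relatives (0.622). The median change of all tested miRNAs was -0.27 in wild type cells at 12 h and -0.0872 in the knockout, and -0.55 and -0.55 with quantile normalization.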

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

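The tests of explanations in this part, other than the count of splits, were chosen after the results were seen. The comparisons between genotypes themselves were fixed before. A test of the difference between genotypes picked out 17 miRNAs for the 12 h and 23 for the 24 h response. All treated arrays of both genotypes lay at the floor for 8 and 9 of these, and their values, wild type minus knockout, only restate the difference between the untreated genotypes and measure no difference in response. Named among them were miR-222 (0.624), miR-146b (0.305), miR-154* (-0.8), miR-210 (-0.731), miR-543 (-0.699) and miR-376a* (-0.698) at 12 h and miR-222 (0.624), miR-146b (0.305), miR-409-3p (-0.814), miR-154* (-0.8), miR-210 (-0.731) and miR-543 (-0.699) at 24 h. Of the other named miRNAs, those with a whole group at the floor, whose sizes are limited by it, were miR-99a (-1.43), miR-369-5p (-0.81), miR-409-3p (-0.748) and miR-152 (-0.653) at 12 h and miR-149 (1.05), miR-196b (0.653), miR-135a* (-1.97), miR-99a (-1.65) and miR-376a* (-0.682) at 24 h. With no whole group at the floor, the differences in log2 response were miR-129-3p (-1.38), miR-148a (-1.23), miR-434-3p (-0.992) and miR-411 (-0.666) at 12 h and miR-20b (0.59), miR-1224 (-1.75), miR-148a (-1.43), miR-23b (-1.17), miR-434-3p (-0.957) and miR-136 (-0.683) at 24 h. Of these only miR-20b, miR-1224 and miR-23b were measured on all 8 arrays compared, so background or the floor limits the sizes of the others too. Another scaling, summary or background correction of the signal turned the sign of miR-129-3p, miR-148a and miR-409-3p at 12 h and of miR-149, miR-222, miR-20b, miR-135a*, miR-409-3p, miR-154*, miR-543, miR-136 and miR-376a* at 24 h.

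Less room above the floor in the knockout may account for part of the 12 h difference. In 13 of the 15 miRNAs with the more negative wild type change, the wild type fall exceeded the whole distance from the untreated knockout level to the floor; 6 of the 15 lay at the floor on all treated arrays, which fixes this outcome, and of the other 9 it held in 7. At 24 h it held in 6 of 11 such others. A response that depends on ATF6a stays open: 0 of the 55 miRNAs measured on all 8 arrays passed, but their 95% intervals reached as far as 4.5 log2 units, the widest from miRNAs that were higher in run 4. In the 51 others they reached up to 1.71, with 21 within 1 log2 unit of 0 and 0 within 0.5, and a p that misses the threshold does not show equal responses.

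Lower Dlk1-Dio3 miRNAs in untreated knockout cells (median -0.81, or -0.35 with normexp) could have come from a loss of all dim miRNAs. The 65 miRNAs outside the list with similar wild type levels had a median difference of -0.0879, which argues against it. Genotype, the origin of the cell populations and array position remain open, since every knockout array had the same position number. For the genotype difference over the 3 conditions, 60 miRNAs passed, and 1 of 100 splits of the arrays within conditions, the real one, reached that number. The highest other split gave 56 and the split that follows the replicate numbers 19. This met the bound set beforehand for arguing against chance, but 60 lies close to 56 and only 108 distinct splits exist. The splits were run with the main scaling alone, and 52 of the 60 miRNAs were not measured on all arrays. Chance is therefore not excluded. Among the 34 splits, the real one included, that put as many arrays of each run on either side, the highest other gave 28.

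For viral miRNAs that were not tested, outside the study's comparisons, 2 exceeded every untreated array on treated ones. mghv-miR-M1-6 reached a log2 signal of -4.08 in wild type cells at 12 h, well above background, and -3.34 in knockout cells at 12 h, not well above the background of that array, both in run 4. mcmv-miR-M23-1-5p in knockout cells at 24 h was at -4.90 in run 3, well above background, and at -4.82 in run 4, not well above it.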

How the results depend on the processing

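Array weights, miRNAs measured on every array compared, run 4 left out, normexp on the median signal, the block with exchanged numbers and run as a block in camera were chosen after the data were seen; normexp on the mean signal was not run. Counts below are of miRNAs past limma's threshold, given where they moved by over 1.5 times, and in full for the replicate block and for its form with exchanged numbers. With run 4 left out every treated group held 1 array, so the spread came from the untreated arrays alone, which varied less, and those counts do not show what treated replicates would support. Scaling on all probes rests on probes below background, since at most 15.9% of probes per array were well above it. Restricting to measured miRNAs tests fewer miRNAs. The cause of the other shifts was not tested. With scaling on all probes, counts were 0 (wild type 12 h, wild type 24 h, knockout 12 h, knockout 24 h, genotype untreated, genotype 12 h, genotype 24 h, genotype mean, difference 12 h, difference 24 h, 24 against 12 h wild type, 24 against 12 h knockout, with 0 to 13 at an unadjusted p under 0.05). With quantile normalization, counts were 15 (wild type 12 h), 11 (wild type 24 h, knockout 12 h), 12 (genotype untreated), 0 (genotype 12 h, genotype 24 h, difference 12 h, difference 24 h, 24 against 12 h wild type, 24 against 12 h knockout, with 2 to 16 at an unadjusted p under 0.05), 1 (genotype mean). With scaling on the median of the common probes, counts were 19 (knockout 12 h), 14 (difference 24 h), 4 (24 against 12 h wild type). With the summed signal of the scanner software, counts were 29 (wild type 12 h), 27 (wild type 24 h), 10 (knockout 12 h), 9 (knockout 24 h), 8 (genotype untreated), 0 (genotype 12 h, genotype 24 h, 24 against 12 h wild type, 24 against 12 h knockout, with 6 to 12 at an unadjusted p under 0.05), 2 (genotype mean, difference 12 h, difference 24 h). With the deposited log2 table, counts were 0 (wild type 12 h, wild type 24 h, knockout 12 h, genotype 12 h, genotype 24 h, genotype mean, difference 12 h, difference 24 h, 24 against 12 h wild type, 24 against 12 h knockout, with 3 to 28 at an unadjusted p under 0.05), 3 (knockout 24 h), 1 (genotype untreated). With the brightest probe per miRNA, counts were 7 (24 against 12 h knockout). With miRNAs detected on all 12 arrays, counts were 19 (wild type 12 h, wild type 24 h), 8 (knockout 12 h), 7 (knockout 24 h), 0 (genotype untreated, difference 12 h, difference 24 h, 24 against 12 h wild type, with 2 to 5 at an unadjusted p under 0.05), 1 (genotype 12 h, genotype mean, 24 against 12 h knockout), 2 (genotype 24 h). With no filter on dim probes, counts were 49 (wild type 12 h), 14 (knockout 12 h), 4 (genotype 12 h), 15 (difference 24 h), 0 (24 against 12 h wild type, with 16 at an unadjusted p under 0.05), 7 (24 against 12 h knockout). With a floor lowered by a factor of 0.5, counts were 6 (difference 12 h), 9 (difference 24 h), 1 (24 against 12 h wild type). With a fit to the compared groups alone, counts were 0 (knockout 12 h, genotype 12 h, 24 against 12 h wild type, 24 against 12 h knockout, with 6 to 34 at an unadjusted p under 0.05), 95 (genotype untreated), 3 (genotype 24 h), 10 (difference 12 h), 42 (difference 24 h). With a replicate block, counts were 85 (wild type 12 h), 73 (wild type 24 h), 34 (knockout 12 h), 25 (knockout 24 h), 53 (genotype untreated), 13 (genotype 12 h, difference 12 h), 20 (genotype 24 h), 60 (genotype mean), 19 (difference 24 h), 2 (24 against 12 h wild type), 4 (24 against 12 h knockout). With run as a fixed block, counts were 5 (24 against 12 h wild type), 8 (24 against 12 h knockout). With run as a random block, counts were 23 (genotype 12 h), 7 (24 against 12 h knockout). With normexp on the median signal, counts were 5 (wild type 12 h, knockout 12 h), 9 (wild type 24 h), 4 (knockout 24 h), 1 (genotype untreated, genotype 24 h, 24 against 12 h knockout), 0 (genotype 12 h, difference 12 h, difference 24 h, 24 against 12 h wild type, with 1 to 6 at an unadjusted p under 0.05), 6 (genotype mean). With miRNAs measured on every array compared, counts were 31 (wild type 12 h), 24 (wild type 24 h), 9 (knockout 12 h, knockout 24 h), 20 (genotype untreated), 1 (genotype 12 h, 24 against 12 h knockout), 5 (genotype 24 h), 3 (genotype mean), 0 (difference 12 h, difference 24 h, 24 against 12 h wild type, with 2 to 5 at an unadjusted p under 0.05). With run 4 left out, counts were 66 (knockout 12 h), 52 (knockout 24 h), 95 (genotype untreated), 53 (genotype 12 h), 43 (genotype 24 h), 96 (genotype mean), 70 (difference 12 h), 82 (difference 24 h), 23 (24 against 12 h wild type), 13 (24 against 12 h knockout). With array weights, counts were 16 (knockout 12 h), 34 (knockout 24 h), 93 (genotype untreated), 5 (genotype 12 h), 9 (difference 12 h), 51 (difference 24 h), 4 (24 against 12 h wild type), 2 (24 against 12 h knockout). Deviations from the group means correlated across miRNAs at 0.74 between the untreated genotypes and at 0.82 to 0.94 between treated groups. Between untreated and treated groups the correlation was -0.66 to -0.45, so arrays of the same number shared no deviation in 1 direction across slides. Replicate number and run coincide within a slide, so this cannot show whether the cultures were paired. The replicate block moved no count by over 1.5 times. With the untreated numbers exchanged, the counts were 87 (wild type 12 h), 74 (wild type 24 h), 42 (knockout 12 h), 25 (knockout 24 h), 52 (genotype untreated), 17 (genotype 12 h), 19 (genotype 24 h), 63 (genotype mean), 14 (difference 12 h), 18 (difference 24 h), 2 (24 against 12 h wild type), 4 (24 against 12 h knockout). Without each array in turn, where a group left with 1 array is assumed to vary like the others, counts ranged over 55 to 94 (wild type 12 h), 53 to 87 (wild type 24 h), 13 to 72 (knockout 12 h), 8 to 32 (knockout 24 h), 35 to 65 (genotype untreated), 6 to 35 (genotype 12 h). The remaining ranges were 9 to 29 (genotype 24 h), 55 to 78 (genotype mean), 10 to 34 (difference 12 h), 11 to 45 (difference 24 h), 0 to 7 (24 against 12 h wild type), 0 to 56 (24 against 12 h knockout). Pearson's r between genotypes at 12 h moved to 0.60 with the summed signal of the scanner software and 0.72 with the deposited log2 table, and ranged from 0.59 to 0.89 without an array. Pearson's r between genotypes at 24 h moved to 0.49 with the summed signal of the scanner software and 0.54 with the deposited log2 table, and ranged from 0.51 to 0.76 without an array. camera called 29 of 168 list tests, 5 with an estimated correlation, and fry 34; with a replicate block camera called 34. Of the single miRNAs recomputed under the alternatives, 4114 values kept direction and side of the threshold, 1400 lost the threshold, 12 gained it and 90 changed sign. The log2 differences that changed sign follow. With the deposited log2 table these were miR-148a 0.58, miR-495 2.28, miR-127 1.32, miR-434-5p 1.41 (wild type 12 h), miR-149 -0.60, let-7b -0.0819, miR-127 0.30 (wild type 24 h), miR-26a 0.40, miR-218 2.95, miR-127 1.80 (knockout 12 h), miR-222 1.84, miR-127 1.23 (knockout 24 h), miR-129-3p 0.13, miR-10a 0.90 (genotype untreated), miR-130b -2.96, miR-10b -0.15, miR-378 -0.62, miR-322 0.20, miR-96 0.79, miR-155 0.37 (genotype 12 h), miR-135a* -0.70, miR-378 -0.34, miR-10a 0.93, miR-196a 0.36, miR-183 0.0102, miR-20b 0.89 (genotype 24 h), miR-378 -0.0307, miR-130b -2.13, miR-96 0.0188, miR-410 0.0834, miR-155 0.0283 (genotype mean), miR-129-3p 0.15, miR-148a 1.04 (difference 12 h), miR-149 -0.99, miR-20b -0.41 (difference 24 h), miR-689 -0.94, miR-148a -0.12, miR-301a -0.0541, miR-96 -0.38, miR-34a -0.24 (24 against 12 h wild type), miR-689 -0.48 (24 against 12 h knockout). Under the summed signal of the scanner software these were miR-127 0.89 (wild type 12 h), miR-149 -2.21, miR-196b -0.68, miR-127 0.53 (wild type 24 h), miR-689 -1.22, miR-26a 0.12, miR-218 0.16, miR-127 1.52 (knockout 12 h), miR-127 1.48 (knockout 24 h), miR-10a 0.34 (genotype untreated), miR-130b -1.43, miR-10b -0.55, miR-378 -0.26, miR-96 0.39 (genotype 12 h), miR-135a* -1.24, miR-689 -0.0786, miR-20b 0.35 (genotype 24 h), miR-130b -0.86, miR-689 -0.81 (genotype mean), miR-409-3p 0.10 (difference 12 h), miR-149 -0.97, miR-222 -1.40, miR-20b -0.43, miR-135a* 1.24 (difference 24 h), miR-689 -0.27 (24 against 12 h wild type). Using normexp on the median signal these were miR-376b 0.0892, miR-210 0.0473 (wild type 24 h), miR-218 0.0582, miR-210 0.0776, miR-146a 0.048 (knockout 24 h), miR-222 -0.0262, miR-218 -0.0597, miR-378 -0.0645, miR-146b -0.0238 (genotype untreated), miR-378 -0.10, miR-99a -0.15 (genotype 24 h), miR-378 -0.053, miR-130b -0.0453, miR-218 -0.14, miR-222 -0.16 (genotype mean), miR-409-3p 0.0478, miR-154* 0.00313, miR-543 0.0875, miR-376a* 0.12 (difference 24 h). With scaling on all probes these were miR-19b -0.71, miR-20b -0.55 (knockout 12 h), miR-148a -0.0194 (knockout 24 h), miR-136 0.0948 (difference 24 h). Under quantile normalization these were miR-20b -0.27 (knockout 12 h). Signal over background limits all counts: 73 to 166 of the tested miRNAs were well above it per array.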

Other observations

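The tests of explanations in this part were chosen after the result was seen, and each replaced an earlier form or bound that had also been run. The camera tests of the Sfmbt2 list were fixed before. In 13 miRNAs, signals in run 4 exceeded those in run 3 by over 1 log2 unit in all 4 treated groups, with a median of 3.35. Of these, 9 stand in the list named for the Sfmbt2 intron cluster, and the others were miR-574-3p, miR-574-5p, miR-877* and miR-1187. That list was written by family name, and the location of each member was not checked. Their median level at 12 h in wild type cells was -4.27 in replicate 1 and -0.28 in replicate 2, and in knockout cells -3.62 and -0.02. The Sfmbt2 list had a camera adjusted p of 0.00136 for wild type cells at 12 h and an adjusted p of 0.534 with an estimated correlation; at 24 h these were 0.0352 and 0.902, and in knockout cells at 12 h 0.00113 and 0.536. At 12 h in wild type cells 0 of its 11 tested members passed alone.

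An added background that lifts every dim miRNA on the run 4 arrays is argued against. The 122 other miRNAs no brighter in run 3 than the brightest of the 13 changed by a median of -0.0527. They were not matched to the 13 in level. The 78 of them above the floor on all run 3 arrays changed by a median of -0.186. The earlier form, over 15 miRNAs not detected in run 3, gave 0 but was fixed by the floor. Higher levels lasting in the replicate 2 cultures, as the whole cause, are argued against whichever untreated array belongs to them: the members differed by a median of -0.441 between untreated replicates 2 and 1, by at most 0.868 in size, and all 13 lay lower on every untreated array than on any run 4 array. An earlier bound, within 0.25 of 0, had left this open, and another, in 1 direction only, had argued against it. A smaller share or cultures with no untreated array stay open. Hybridisation of non-target RNA may contribute: 3 of 97 viral miRNAs and markers of other cell types had a mean rise over 1 log2 unit, mghv-miR-M1-2 by 1.88, miR-294 by 1.33 and miR-206 by 1.22. The earlier form asked for such a rise in all 4 pairs, found 0, and by its own bound had argued against this explanation, so the choice of form decides and it stays open. The 97 were not matched to the 13 in sequence, so neither form tests hybridisation through a sequence that the 13 may share. The design gives no group that separates the runs, so no other biological explanation was tested.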
